A study of Homo sapiens with 60 samples.

How the data were processed

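The measurement was amplicon sequencing of an integrated pool of 6-base translation initiation sequences in HEK293T cells. Per the labels, 6 µg of the library and 6 µg of the plasmid for Cas9 with the AAVS1 guide, or of the hyPBase plasmid, were transfected together, puromycin at 2 µg/ml was added after 48 h, and selection lasted at least 10 days. Genomic DNA was extracted, the insert was amplified with a proofreading polymerase while amplification was exponential, and the products were sequenced from a PCR-free preparation. The deposited values are raw counts of reads per 6-base sequence, 1 table for each of the 60 libraries. The program that parsed or counted the reads is not given in the sources used here. Sequences without a read are not listed, and they were entered as 0 among the 4096 possible variants. All listed values were whole numbers of at least 1.

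Libraries were grouped by their titles into 15 groups of 4, from 3 arms and 5 fractions. Tests, filters, sequence classes, named variants and most other settings were chosen before the data were examined. Library totals between 440948 and 5300552 reads set the precision, and a variant without a read in a group was given the limit of 3 reads over the group's total, set after the data were seen.

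Variants were tested with edgeR 4.0.16 under R 4.3.3, using robust quasi-likelihood F tests with library totals as the scaling, a group mean per fraction and all 20 libraries of an arm in the fit. Variants with at least 10 reads in at least 4 libraries of the arm were tested, 4096 in the CRISPR-Cas9 and PiggyBac arms and 2757 in the 100x arm. Contrasts were each fraction against background, high against low, and a linear slope over low, medium, high and ultra high with weights of -1.5, -0.5, 0.5 and 1.5 divided by 5. The difference between arms in high versus low was tested as an interaction on the 16 high and low libraries of a pair of arms. Benjamini-Hochberg adjusted p under 0.05 counted as passing. The common biological coefficient of variation was 1.06 in the CRISPR-Cas9 arm, 0.949 in the PiggyBac arm and 1.68 in the 100x arm.

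The variants to name were, per arm, the 5 with the highest and the 5 with the lowest change in high versus low among those that passed with a mean of at least 50 reads over low, medium and high, the 3 with the smallest p in each interaction that passed, and 10 fixed variants. The fixed ones were the 4 forms of GCCNCC (N is any base), ACCACC, CAAACA and the runs of 6 equal bases. No variant of the 100x arm passed with a lower value in high than in low, so that arm names 5.

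The 18 sequence classes were tested with camera of limma 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, in high versus low and in the slope of each arm, with adjustment over all 108 tests. The class effect is the mean of the class minus the mean of all other variants, given as the mean and SD of the 4 differences between same-numbered libraries. Library coverage was compared between the background libraries of the arms by exact two-sided permutation tests (12 tests), and the share of reads with each base at each position by the same test within arms (144 tests), each family adjusted as a whole. Correlations between arms were computed across variants.

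The numbers of the libraries were checked for pairing through the deviations of log2 CPM from the fraction means. Same-numbered libraries of the 100x arm correlated at 0.492 to 0.866 for every pair of fractions, those of the CRISPR-Cas9 arm at 0.0645 to 0.525, under the bound of 0.1 for low and ultra high, and those of the PiggyBac arm at -0.0139 to 0.121, while different numbers reached at most 0.0239, 0.0415 and -0.133 in the CRISPR-Cas9, PiggyBac and 100x arms. A fit with the number as a block is therefore given where it changed a call.

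The settings fixed in advance were TMM scaling, DESeq2 1.42.0 with its own size factors, no filter and a filter of 50 reads, the replicate block, only the compared fractions in the fit, each number and each single library left out, thinning of the background libraries to 1575160 reads, a minimum of 100 reads, each variant counted once, an estimated correlation, the self-contained test fry, and prior counts of 0.5 and 5. Chosen after the data were seen were the subtraction of reads expected from other libraries, the sign permutation of same-numbered differences in base shares, the tests of purines at -3 between arms, with and without the subtraction, and splits of the CRISPR-Cas9 and 100x arms with fractions permuted within each number. To ask whether class effects follow from the base at -3, the mean log2 CPM of the variants with each base at -3 was subtracted in every library, and camera was run again, adjusted over 9 classes in each of 2 arms. For the subtraction, the share that 1 library receives from another of its fraction was the median ratio of reads over the top 20 variants of the source. That share was subtracted in all 100x libraries and in the ultra high libraries of the other arms, and in the 100x high libraries the share that matched the same-numbered CRISPR-Cas9 medium library was subtracted as well.

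The tests were run on simulated data with the size and spread of each arm. For high versus low, edgeR recovered 0%, 31.8% and 89.4% of variants changed by 2, 4 and 6 log2 units in the CRISPR-Cas9 arm, and 7.35%, 59.1% and 90.9% in the PiggyBac arm, each from 66 to 68 changed variants of 4096, with 5 and 2 false calls. In the simulated 100x arm, 2757 variants, it recovered 0% at each of these sizes. The larger sizes were added after the recovery at 2 and 4 was seen. A further simulation changed 200 variants by rises and falls of 2 to 8 log2 units. Of those changed by 8, edgeR recovered 94%, 100% and 0% in the CRISPR-Cas9, PiggyBac and 100x arms. The recovery of its smaller changes was not computed. False calls numbered 41 and 699 in the CRISPR-Cas9 and PiggyBac arms, since large rises take read share from all other variants under scaling by totals. In the 100x arm there were 0. The camera test gave an unadjusted p under 0.05 for a shift of 1 in the single class simulated per arm. That class held 1024 variants in the CRISPR-Cas9 and PiggyBac arms and 689 in the 100x arm. Smaller classes were not simulated. The permutation test recovered 100% of 200 shifts of 6 SD, and 2.8% of 500 tests without a shift had a p under 0.05. Shares, permutations and figures were computed with Python 3.11.15, numpy 2.4.6 and matplotlib 3.10.9.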

Results

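Translation initiation sequences are the bases just ahead of a start codon, and they influence how readily a ribosome begins there. A pool of constructs that differed in 6 of these bases, 4096 possible variants, was integrated into the genome of HEK293T, a human embryonic kidney cell line, to learn how the bases affect the efficiency of translation. The 60 libraries were amplicons of the insert from genomic DNA, so the read share of a variant describes its share of the integrated copies in a sample, not a level of RNA or protein. They formed 3 arms of 20 libraries. In the CRISPR-Cas9 arm the pool was delivered with a Cas9 plasmid whose guide is named for AAVS1, a safe-harbour site in the PPP1R12C gene. In the PiggyBac arm it was delivered with a plasmid for hyPBase, a hyperactive transposase that can insert cargo at many sites of the genome. The third arm carries the label 100x CRISPR-Cas9, and what 100x refers to is not stated in the labels. Each arm held 5 fractions, named background, low, medium, high and ultra high, with 4 numbered libraries in each. How the fractions were obtained, and whether background stands for unsorted cells, is not stated either.

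Library totals ran from 440948 to 5300552 reads. Group means lay between 638240 ± 168865 reads (SD, n = 4) in PiggyBac low and 4270980 ± 750677 reads (SD, n = 4) in PiggyBac background. The low, high and ultra high fractions of the CRISPR-Cas9 arm held 817225, 1332870 and 1530190 reads on average, and those of the 100x arm 892476, 2804640 and 924152 reads. No pair of same-group libraries held identical values, and the most similar pair differed by a chi-square of 55.4 per degree of freedom, far above sampling noise. The labels do not say that same-group libraries came from separate cultures, so no p-value here can be read as measuring a spread between cultures. Those of edgeR, DESeq2 and the permutation tests measure the spread between these samples, which may be technical. Those of camera set the variants of a class against all other variants, with a preset or estimated correlation between variants. No start codon is shown beside the 6 listed bases, and counting them as positions -6 to -1 is an assumption. Where a group held no read of a variant, the upper limit given is 3 reads over the group's total. PCR reads without molecular identifiers are not independent molecules, so such limits cover counting error only.

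The pool was almost complete in the background cells of both ordinary arms and far from complete in the 100x arm. At least 1 read was found for 4091 ± 4.79 (SD, n = 4) of the 4096 variants in the CRISPR-Cas9 background, for 4096 ± 0 (SD, n = 4) in the PiggyBac background and for 2667 ± 278 (SD, n = 4) in the 100x background. At least 10 reads were found for 4062 ± 15, 4086 ± 9.95 and 1171 ± 130 variants in the same order. The most abundant 1% of variants, 41 sequences, took 9.05% ± 1.34, 8.23% ± 0.611 and 77.7% ± 4.92 of the reads (SD, n = 4 each). Read counts were also spread more evenly in the PiggyBac background than in the CRISPR-Cas9 one. Gini coefficients, where 0 is an even spread, were 0.396 ± 0.00712 and 0.474 ± 0.0196 (SD, n = 4 each), against 0.980 ± 0.00316 in the 100x background.

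Of the 12 comparisons of background libraries between arms, 10 passed (exact two-sided permutation test, 4 against 4, p = 0.0286, the smallest possible, adjusted p = 0.0343). The exceptions were both between PiggyBac and CRISPR-Cas9: 24.3 more variants with at least 10 reads (exact p = 0.0571, adjusted p = 0.0623) and 0.817 percentage points between the top shares in the opposite order (exact p = 0.343, unchanged by adjustment). Of the 10, the difference of 5.25 variants with at least 1 read between PiggyBac and CRISPR-Cas9 did not pass with the libraries thinned to an equal total (4.25, exact p = 0.2, adjusted p = 0.218). Along the fractions, the ultra high libraries held the fewest variants. At least 10 reads were found there for 1669 ± 177 variants in the CRISPR-Cas9 arm, 1683 ± 236 in the PiggyBac arm and 235 ± 36.3 in the 100x arm (SD, n = 4 each).

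**Figure D1:**
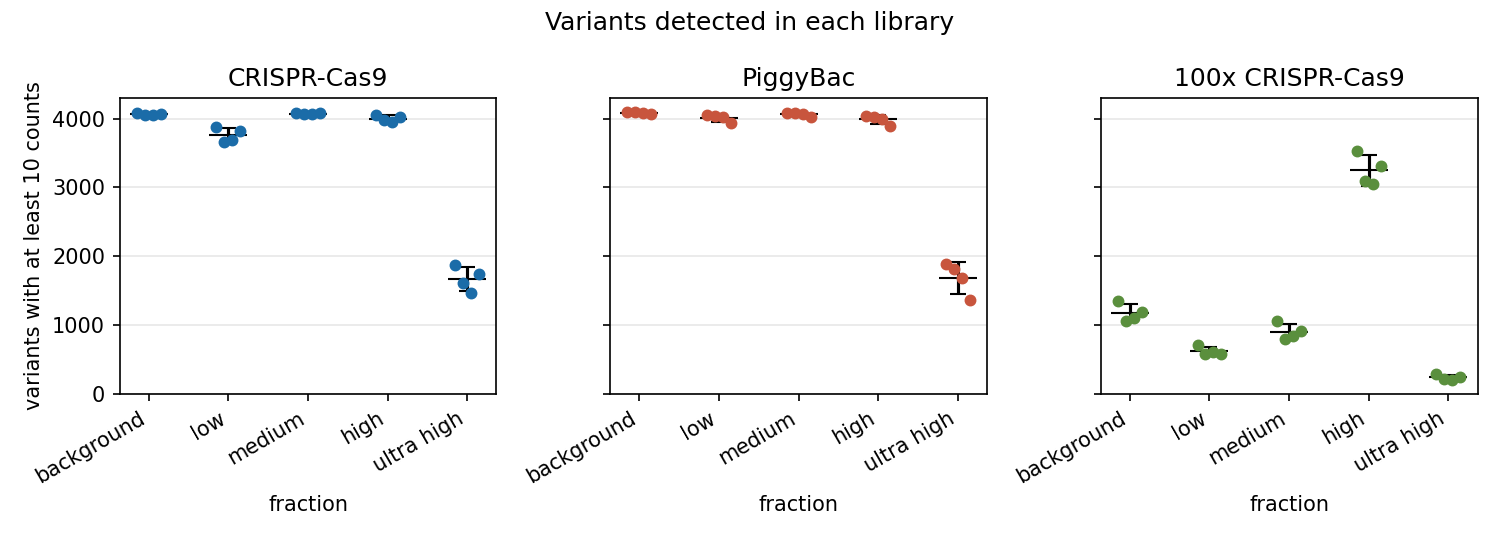
Number of variants with at least 10 reads (y axis) in each library (points) by fraction (x axis), with 1 panel per arm and the mean of the 4 libraries with its SD. The ultra high libraries hold at most 1867 variants in the CRISPR-Cas9 arm and 1889 in the PiggyBac arm, and the 100x high libraries, with 3047 to 3527 variants, lie above their background libraries, with 1056 to 1348.

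A purine at -3, the position of the Kozak consensus GCCRCC (R is A or G) best known for its role in start codon recognition, set the high fraction of the CRISPR-Cas9 arm apart from the low fraction. Purines at -3 took 73.2% ± 1.38 of the reads in the high libraries and 29.3% ± 4.05 in the low libraries, with 53.4% ± 0.358 in the background and 44.9% ± 1.68 in the medium fraction (SD, n = 4 each). With every variant weighted equally, variants with a purine at -3 rose by 2.27 ± 0.03 on the log2 scale of high over low, relative to the other variants (SD, n = 4 differences between same-numbered libraries, all above 0). A at -3 rose by 1.83 ± 0.05 and G by 1.20 ± 0.06, while C fell by 1.10 ± 0.05 and T fell by 1.93 ± 0.06 (SD, n = 4 each). In limma's camera test the adjusted p was 9.84e-59 for purines and ranged up to 2.58e-09 for the single bases, and with an estimated correlation between variants the adjusted p for purines was 1.32e-09.

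**Figure D2:**
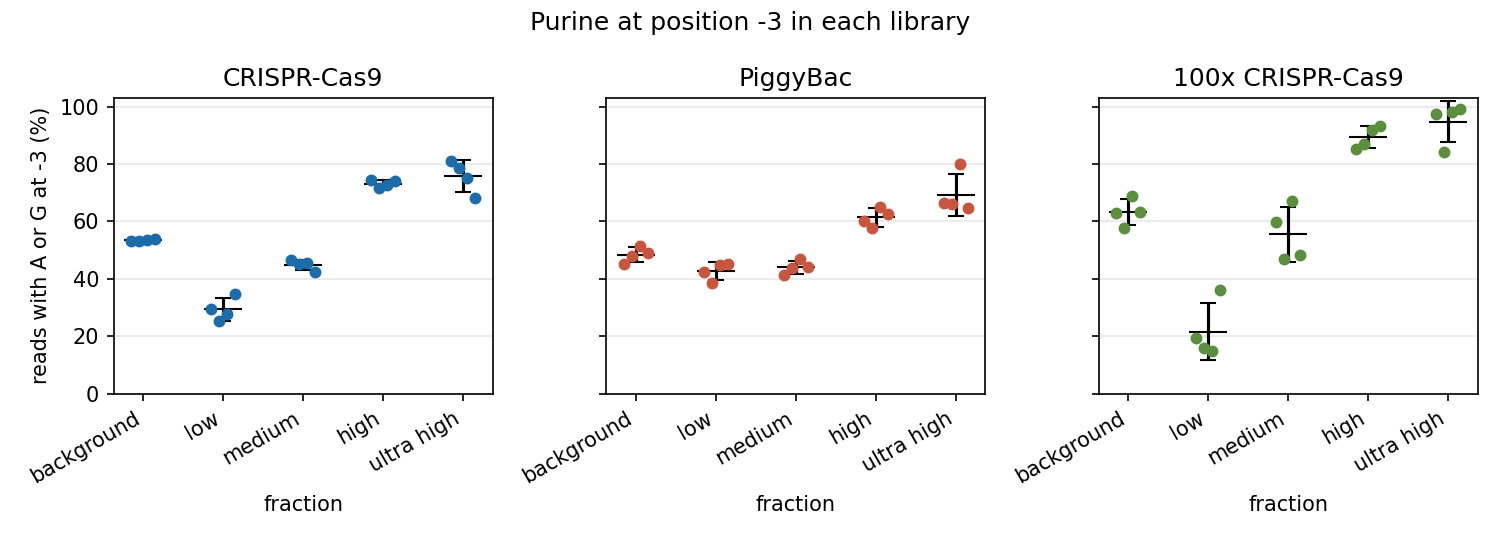
Share of reads with A or G at the assumed position -3 (y axis, percent) in each library (points) by fraction (x axis), with 1 panel per arm and the mean of the 4 libraries with its SD. By group means the share lies lowest in the low fraction and highest in the ultra high fraction of each arm, from 29.3% to 75.8% in the CRISPR-Cas9 arm, 42.7% to 69.2% in the PiggyBac arm and 21.6% to 94.7% in the 100x arm.

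Of the 18 sequence classes fixed before the data were examined, as were the tests and most other settings tried, 15 passed in the CRISPR-Cas9 high versus low comparison. Besides the classes by base at -3, variants with at least 5 of 6 matches to GCCRCC rose by 1.27 ± 0.18 (34 variants, camera adjusted p = 0.000300; SD, n = 4). Those with at most 1 match fell by 1.40 ± 0.05 (1782 variants, camera adjusted p = 5.11e-16; SD, n = 4). Upstream ATG triplets, which can start translation ahead of the intended site, were grouped by reading frame. All their places but -6 to -4 also set the base at -3. In-frame ones rose by 0.59 ± 0.17 (127 variants, camera adjusted p = 0.0241; SD, n = 4). Out-of-frame ones fell by 0.86 ± 0.08 (128 variants, camera adjusted p = 0.000299; SD, n = 4). Within each frame the places differed. In-frame ATG stood at -0.13 at -6 to -4 and at 1.32 at -3 to -1. Out-of-frame ATG stood at -0.30 at -5 to -3 and at -1.42 at -4 to -2. Frame alone therefore does not describe these values. In-frame stop codons fell by 0.66 ± 0.08 (375 variants, camera adjusted p = 0.00201; SD, n = 4). With the mean of each base at -3 removed from every library, in-frame ATG (-0.10 ± 0.16) and in-frame stop codons (0.12 ± 0.10) turned in sign and did not pass (SD, n = 4; camera adjusted p = 0.579 and 0.465). Sequences with CTG or GTG, triplets that can act as weak start codons, fell by 0.44 ± 0.07 (492 variants, camera adjusted p = 0.0360; SD, n = 4).

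Runs of a single base also moved apart. Variants with at least 4 A rose by 0.76 ± 0.12 (camera adjusted p = 0.000499; SD, n = 4). Those with at least 4 T fell by 1.46 ± 0.20 (camera adjusted p = 9.36e-10) and those with at least 4 C fell by 0.50 ± 0.03 (camera adjusted p = 0.0371; 154 variants and n = 4 each, SD). The 16 variants that hold GTAAG or GTGAG, which resemble a 5' splice site, rose by 1.54 ± 0.91 (camera adjusted p = 0.00271; SD, n = 4). GC-rich variants, AT-rich variants and variants with at least 4 G did not pass (camera adjusted p = 0.855, 0.217 and 0.427). Removing the base at -3 in the same way also ended the calls of at least 4 A (-0.09 ± 0.12), at least 5 matches (0.24 ± 0.19), GTAAG or GTGAG (0.29 ± 0.93) and CTG or GTG (-0.29 ± 0.08; SD, n = 4; camera adjusted p = 0.760, 0.465, 0.586 and 0.0972). For CTG or GTG the adjusted p was 0.000625 with an estimated correlation. On the deposited counts all 15 calls held with an estimated correlation. Leaving out the number 3 libraries ended the calls of the in-frame ATG class (adjusted p = 0.0521) and of CTG or GTG (adjusted p = 0.0537), and leaving out the number 4 libraries ended that of at least 4 C (adjusted p = 0.0567).

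**Figure D3:**
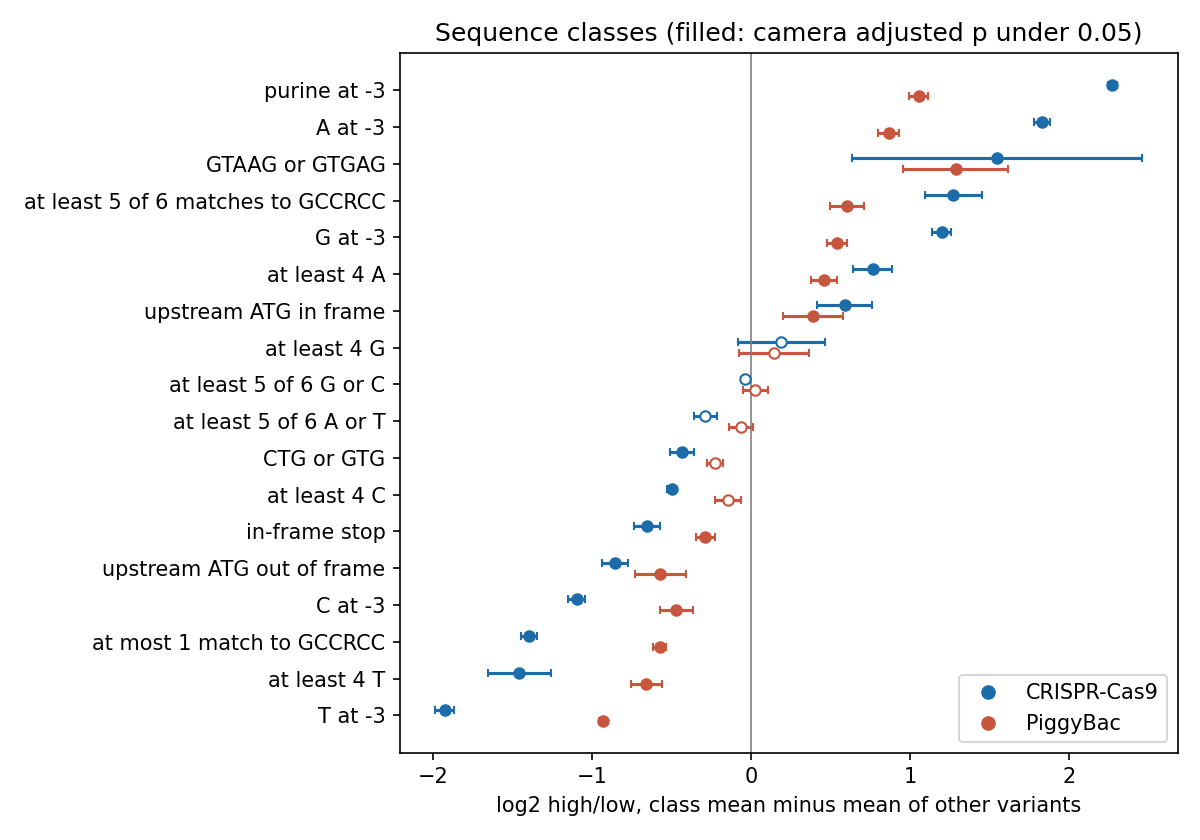
Effect of the 18 sequence classes (y axis) in high versus low of the CRISPR-Cas9 and PiggyBac arms (x axis, log2 of high over low, mean of the class minus the mean of all other variants), where points are means of the 4 numbers, bars their SD, filled points classes with a camera adjusted p under 0.05 and open points the others. The CRISPR-Cas9 values reach from -1.93 for T at -3 to 2.27 for purines at -3, and the PiggyBac values from -0.93 for T at -3 to 1.28 for GTAAG or GTGAG.

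In high versus low of the CRISPR-Cas9 arm, the read shares of bases at other positions differed less than those at -3. A at -3 took 46.7% ± 1.54 of the high reads and 17.3% ± 3.54 of the low reads, and T at -3 took 11.2% ± 0.920 and 39.1% ± 3.35 (SD, n = 4 each). G at -2 took 21.1% ± 1.76 and 33.0% ± 1.12, and T at -1 took 18.3% ± 1.29 and 28.7% ± 3.50 (SD, n = 4 each). All 4 shares separated the libraries fully (exact two-sided permutation p = 0.0286), but none of the 144 composition tests passed after adjustment, since the smallest p that 4 against 4 libraries allow gave an adjusted p of 0.133. At that smallest p stood 13 of the 24 shares in CRISPR-Cas9 high versus low, 3 in the PiggyBac arm and 5 in the 100x arm.

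**Figure D4:**
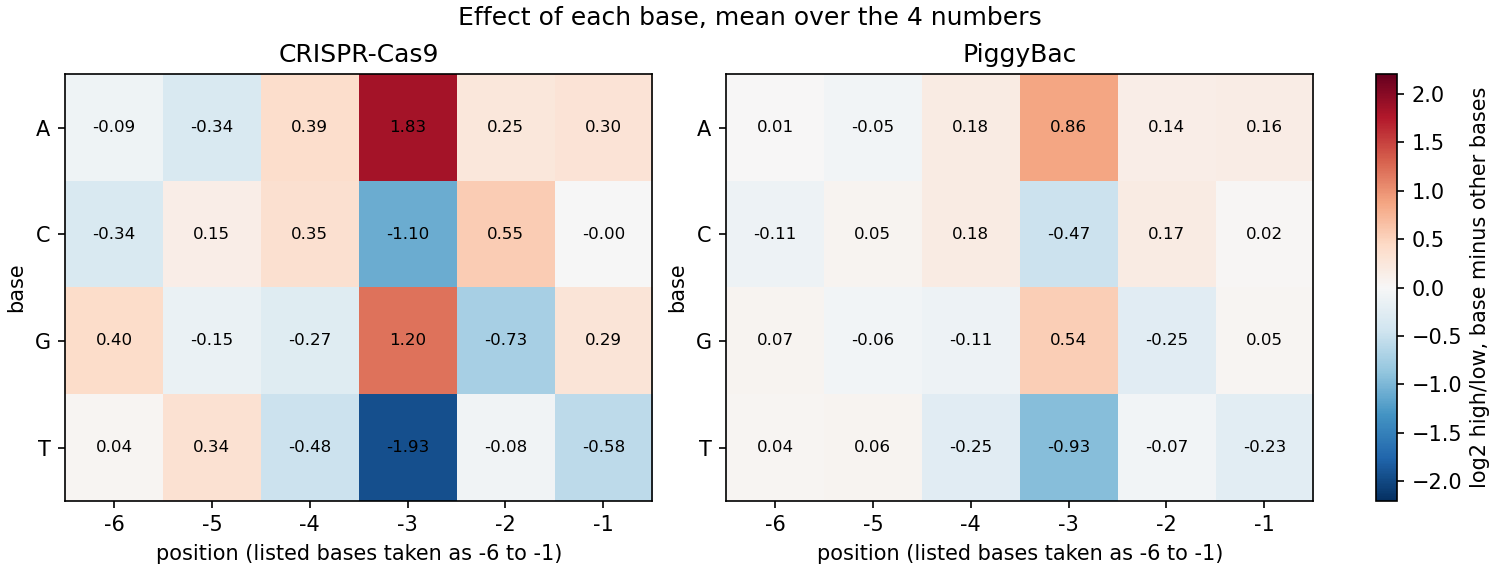
Heat map of the effect of each base (rows) at each assumed position from -6 to -1 (columns) in high versus low, with 1 panel for the CRISPR-Cas9 arm and 1 for the PiggyBac arm, where colour and printed number are the mean over the 4 numbers of the log2 of high over low for variants with the base minus that for all other variants. The effects at -3 reach 1.83 for A and -1.93 for T in the CRISPR-Cas9 arm, and the largest at any other position of that arm is -0.73, for G at -2.

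Of the 10 variants fixed in advance, TTTTTT set the fractions of the CRISPR-Cas9 arm furthest apart. It averaged 4083 ± 3211 CPM (counts scaled to an equal library total) in the low libraries and 48.1 ± 52.0 CPM in the high ones (SD, n = 4 each), lower in the high library for each of the 4 numbers, with a log2 change of -6.41 ± 1.61 (SE). It passed in edgeR with p-values adjusted over the list alone (adjusted p = 0.00341, 1 of the 10 variants) and not over all variants (adjusted p = 0.104), and DESeq2 gave -6.81 with an adjusted p of 3.98e-07 over all variants. CCCCCC averaged 3088 ± 5350 and 252 ± 70.3 CPM, and GCCGCC, a full match to the Kozak consensus, 92.6 ± 49.5 and 245 ± 152 CPM (SD, n = 4; edgeR adjusted p over all variants 0.179 and 0.494). For GCCACC, the other full match, the low libraries averaged 565 ± 946 and the high ones 269 ± 102 CPM (SD, n = 4; edgeR adjusted p = 0.634), and the log2 change of -1.07 became 1.54 without low library 1. Over all variants edgeR called 0 of 4096, with 801 at an unadjusted p under 0.05, while DESeq2 called 556, of which 151 were higher and 405 lower in the high fraction. Leaving out low library 4 gave 8 edgeR calls.

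In the PiggyBac arm the same bases at -3 separated high from low, with smaller values. Purines at -3 took 61.4% ± 3.22 of the high reads and 42.7% ± 3.01 of the low reads, with 48.4% ± 2.68 in the background (SD, n = 4 each). With equal weight per variant, purines at -3 rose by 1.05 ± 0.06, A by 0.86 ± 0.07 and G by 0.54 ± 0.06, while C fell by 0.47 ± 0.10 and T fell by 0.93 ± 0.02 (log2, SD, n = 4; camera adjusted p from 6.66e-32 for purines to 1.10e-05 for C). At least 5 matches to GCCRCC rose by 0.60 ± 0.11 (camera adjusted p = 0.00384) and at most 1 match fell by 0.58 ± 0.04 (camera adjusted p = 2.23e-08; SD, n = 4).

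The frame classes of upstream ATG triplets, most of whose places set the base at -3, again went opposite ways in the PiggyBac arm. Out-of-frame ones fell by 0.57 ± 0.16 (camera adjusted p = 2.30e-05) and in-frame ones rose by 0.39 ± 0.19 (camera adjusted p = 0.0137; SD, n = 4), a call that ended without the number 2 libraries (adjusted p = 0.0910). In-frame stop codons fell by 0.29 ± 0.06 (camera adjusted p = 0.0224), at least 4 A rose by 0.46 ± 0.08 (camera adjusted p = 0.000248) and GTAAG or GTGAG rose by 1.28 ± 0.33 (camera adjusted p = 4.64e-05; SD, n = 4). At least 4 T fell by 0.66 ± 0.10 (camera adjusted p = 2.27e-06; SD, n = 4), but its adjusted p was 0.125 with an estimated correlation. That was the only one of the 13 calls lost in this way, and CTG or GTG, at an adjusted p of 0.0512, had one of 0.0111 with an estimated correlation. With the mean of each base at -3 removed, in-frame ATG (0.06 ± 0.20), in-frame stop codons (0.09 ± 0.07), at least 4 A (0.06 ± 0.10) and at least 4 T (-0.24 ± 0.11) did not pass (SD, n = 4; camera adjusted p = 0.845, 0.420, 0.589 and 0.0972). Nor did at least 5 matches (0.13 ± 0.10) and at most 1 match (-0.16 ± 0.02; SD, n = 4; camera adjusted p = 0.540 and 0.207), though the last had an adjusted p of 0.000600 with an estimated correlation. Variants with at least 4 C or at least 4 G, and GC-rich or AT-rich variants, did not pass. edgeR called 0 of 4096 variants in PiggyBac high versus low, with 175 at an unadjusted p under 0.05, and DESeq2 called 24. Of the 10 variants fixed in advance 0 passed there in edgeR, adjusted over the list alone or over all variants (smallest adjusted p over the list alone 0.895).

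The ultra high fraction set apart the largest number of single variants in both ordinary arms, mostly through variants that had all but vanished from it. Against the background, edgeR called 2557 of 4096 variants in the CRISPR-Cas9 arm, 75 higher and 2482 lower in the ultra high fraction, and 1755 in the PiggyBac arm, 96 higher and 1659 lower. The top 1% of variants took 63.7% ± 2.81 and 51.7% ± 5.64 of the ultra high reads (SD, n = 4 each), while the median log2 change of all variants was -3.75 and -2.21. These medians were -3.80 and -2.23 with the 393 and 397 variants without an ultra high read set to the limit of 3 reads. With only the ultra high and background libraries in the fit, edgeR called 917 variants in the PiggyBac arm. TMM scaling, which centres most variants near no change, gave 1637 calls, 602 higher and 1035 lower, with a median of -0.34 in the CRISPR-Cas9 arm, and 1368 calls, 428 higher and 940 lower, with a median of -0.20 in the PiggyBac arm. The direction of a variant's change therefore holds only relative to those medians. The dominant variants also differed between ultra high libraries. The top variant was CCTGTC, GAGACG, GAAGCA or ATCCCG in the CRISPR-Cas9 arm, and TTTCGA, CAGAAT, ATGGCG or CGCGTT in the PiggyBac arm. The top 20 variants of a library had a median of 0.622% and 0.696% of those reads in another library of the group. Whether the falls follow from the sequences of the variants was not tested.

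TTTTTT had 231 ± 201 CPM (SD, n = 4) in the CRISPR-Cas9 background and no read in any of the 4 ultra high libraries, which allows up to 0.490 CPM over the group, at least 482-fold below the 236 CPM of the pooled background reads (edgeR adjusted p = 3.29e-05). GCCCCC had 513 ± 244 CPM in the background and 0.389 ± 0.509 CPM, 2 reads in all, in the ultra high libraries (SD, n = 4; edgeR adjusted p = 6.32e-06). CCCCCC had 701 ± 274 and 8.96 ± 9.78 CPM (SD, n = 4; edgeR adjusted p = 0.00112). With GCCTCC and GGGGGG (edgeR adjusted p = 0.00637 and 0.0206), 5 of the 10 fixed variants passed in the CRISPR-Cas9 arm, and also 5 adjusted over the list alone. In the PiggyBac arm GCCTCC had 460 ± 132 CPM in the background and 2.55 ± 1.87 in the ultra high fraction (SD, n = 4; edgeR adjusted p = 9.69e-07), the 1 variant of the 10 to pass there, also when adjusted over the list alone. Over all variants 2557 of 4096 passed in the CRISPR-Cas9 arm and 1755 of 4096 in the PiggyBac arm. The fixed variants thus passed no more often than all variants did. Purines at -3 took 75.8% ± 5.595 of the ultra high reads in the CRISPR-Cas9 arm and 69.2% ± 7.27 in the PiggyBac arm (SD, n = 4 each).

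Over the order low, medium, high, ultra high, the slope per fraction step passed in edgeR for 2365 variants of the CRISPR-Cas9 arm, 224 positive and 2141 negative, and for 1672 of the PiggyBac arm, 122 positive and 1550 negative. With TMM scaling 838 were positive and 1254 negative in the CRISPR-Cas9 arm, the median slope moving from -0.99 to -0.15, and 469 positive and 949 negative in the PiggyBac arm, from -0.62 to -0.06. Of the 10 fixed variants 4 passed by slope in the CRISPR-Cas9 arm, TTTTTT, CCCCCC, GCCCCC and GCCTCC, all negative, and 8 adjusted over the list alone. GCCTCC was the 1 variant of the PiggyBac arm by either adjustment. Purines at -3 had a steeper slope than other variants by 1.00 (log2 per step, camera adjusted p = 3.40e-34) and by 0.67 (camera adjusted p = 8.56e-17). Out-of-frame ATG fell by 0.39 and 0.42 per step relative to the rest (camera adjusted p = 0.000859 and 0.000407). The slope calls of at least 4 G and at least 4 T in the PiggyBac arm, with adjusted p of 0.0360 and 0.00385, were lost with an estimated correlation (adjusted p = 0.399 and 0.355). That of at least 4 G was also lost without the number 3 libraries (adjusted p = 0.0833).

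Against the background, the low, medium and high fractions gave few single calls in these arms. edgeR called 0 variants in all 6 comparisons. In the CRISPR-Cas9 arm 312, 17 and 142 variants stood at an unadjusted p under 0.05 for low, medium and high, and DESeq2 called 113, 0 and 0. In the PiggyBac arm the same counts were 71, 27 and 104, and DESeq2 called 0, 0 and 11.

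In the 100x arm the fractions differed in the base at -3 by the widest margin of reads, and the read counts of few variants carried it. Purines at -3 took 89.4% ± 3.87 of the high reads and 21.6% ± 9.96 of the low reads, with 63.2% ± 4.49 in the background and 94.7% ± 7.14 in the ultra high fraction (SD, n = 4 each). With equal weight per variant purines rose by 0.94 ± 0.09 (camera adjusted p = 0.0492), while T at -3 fell by 1.02 ± 0.01 (camera adjusted p = 0.00915; SD, n = 4). At least 4 T fell by 1.18 ± 0.17 (camera adjusted p = 0.00810; log2 of high over low, SD, n = 4). These were the 3 classes of 18 that passed. All 3 held with an estimated correlation, where A at -3 passed too (adjusted p = 0.0255), and the purine call ended with a prior count of 5 (camera adjusted p = 0.0628). Same-numbered libraries of this arm deviate together, and with the replicate number as a block 7 classes passed. The added ones were A at -3, G at -3, at most 1 match to GCCRCC and at least 4 A (camera adjusted p = 0.000363, 0.0368, 0.00957 and 0.0394). Leaving out the libraries of number 1, 2, 3 or 4 gave 9, 8, 7 and 8 passing classes, and by slope, where 6 classes passed, leaving out number 3 gave 10.

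The high libraries of the 100x arm also held reads of variants that were hardly present in the other fractions of the same number. Depending on the number, 2629 to 2918 variants had at most 10 reads in each of the other 4 fractions, and 2565 to 2743 of these had reads in the high library, 2.56% to 3.31% of its total. Their read counts followed those of the same-numbered CRISPR-Cas9 medium library with a Spearman correlation across variants of 0.789 to 0.817, the highest of 40 libraries in 4 of 4 cases, at 4.69% to 4.83% of the reads in that library. Variants are not independent replicates, so no p-value is attached to these correlations. A subtraction of such reads, chosen after the data were seen, was therefore run beside each count of the 100x arm.

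**Figure D5:**
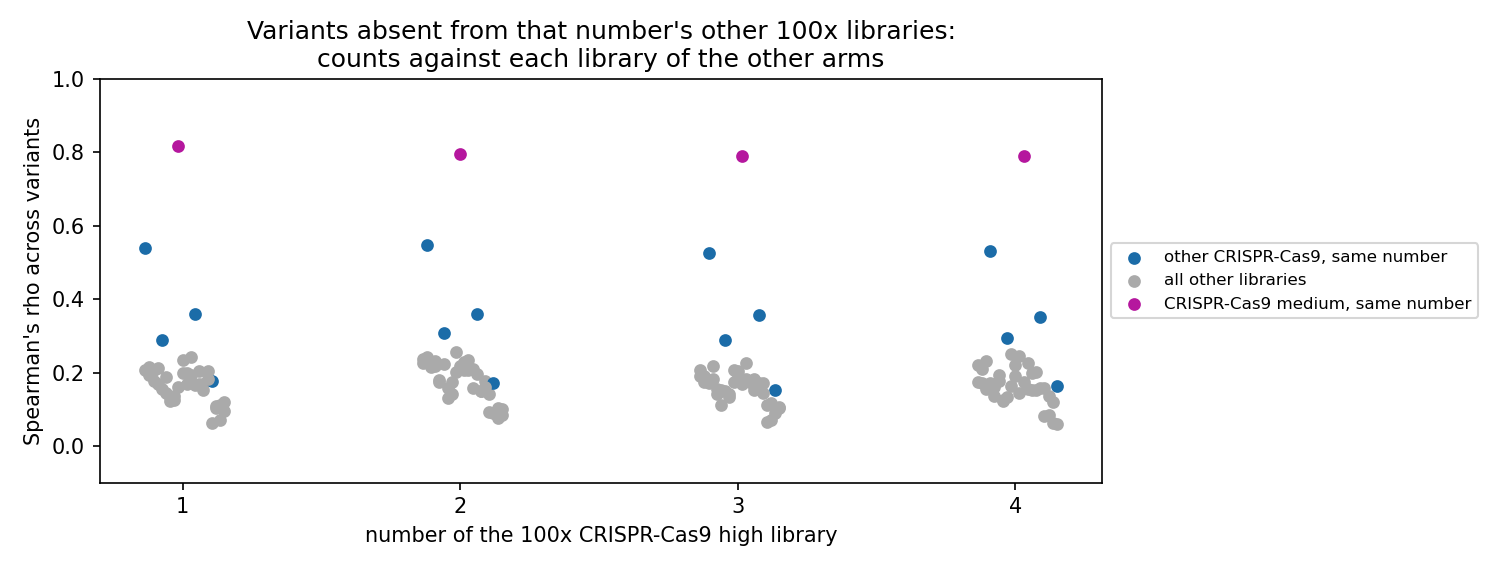
Spearman's rho across variants (y axis) between the reads of variants with at most 10 reads in each other fraction of the same 100x number, in each of the 4 high libraries of the 100x arm (x axis), and the reads of the same variants in each of the 40 libraries of the other arms (points: magenta, the same-numbered CRISPR-Cas9 medium library; blue, other CRISPR-Cas9 libraries of that number; grey, all others). The magenta point is the highest for each number, at 0.789 to 0.817, and the next library lies at 0.526 to 0.547.

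The variants with the highest change in high versus low of the 100x arm were AAAGAA, TGAAGG, GGAATT, AACATA and CCGGCC (edgeR adjusted p between 0.00496 and 0.00891). AAAGAA averaged 358 ± 672 CPM in the high libraries and had no read in the low ones, which allows up to 0.840 CPM over the group and puts the pooled high reads, 308 CPM, at least 366-fold higher. TGAAGG, AACATA and CCGGCC also had no read in the low libraries and were at least 288-fold, 153-fold and 145-fold higher in the pooled high reads (242, 129 and 122 CPM) by the same limit. GGAATT averaged 1305 ± 2494 CPM in the high libraries and had 1 read in the low ones (SD, n = 4). All 5 calls ended without high library 1 (edgeR adjusted p = 0.0537 each), and after the subtraction of cross-library reads 0 variants passed in edgeR, with 82 at an unadjusted p under 0.05. The log2 changes of AAAGAA, GGAATT, AACATA and CCGGCC went in it from 12.60 ± 3.74, 11.78 ± 3.64, 11.33 ± 3.602 and 10.88 ± 3.42 to 12.56 ± 5.00, 11.68 ± 5.43, 10.85 ± 4.63 and 10.79 ± 4.26 (SE; edgeR adjusted p = 0.686, 0.728, 0.686 and 0.686). The SEs rose with the common coefficient of variation, from 1.68 to 2.92, and TGAAGG was not tested. With the block as well, the values were 11.14, 4.37, 8.48 and 10.00 (edgeR adjusted p = 0.209, 0.440, 0.244 and 0.209). Single libraries weighed on each value. The log2 changes of AAAGAA, TGAAGG (12.33), GGAATT, AACATA and CCGGCC became 8.60, 7.86, 7.29, 8.15 and 8.14 without high library 2, 3, 4, 2 and 1. Of the fixed variants, GCCGCC, with 9.42 ± 4.06 CPM in the high libraries and none in the low ones, at least 10.7-fold higher in the pooled high reads (9.003 CPM), and AAAAAA, with 26.7 ± 9.26 and 0.239 ± 0.478 CPM, passed (SD, n = 4; edgeR adjusted p = 0.00619 and 0.0382). Adjusted over the list alone, 1 of the 8 tested passed, GCCGCC (edgeR adjusted p = 0.00843). With TMM scaling both were lost (edgeR adjusted p = 0.0694 and 0.155), as in DESeq2, where the log2 changes of 7.36 and 6.40 became 3.29 and 4.08 (DESeq2 adjusted p = 0.236 and 0.152). GCCGCC was also lost without high library 1, 3 or 4 and AAAAAA without any 1 of the 4 (edgeR adjusted p between 0.0503 and 0.116). After the subtraction AAAAAA had a log2 change of 3.65 (edgeR adjusted p = 0.805). GCCGCC, with 0.383 CPM in the pooled background reads and no read in the ultra high libraries, was then no longer tested. With the replicate block GCCACC, GCCCCC, ACCACC, CCCCCC and CAAACA passed too (edgeR adjusted p = 0.00249, 0.00142, 0.00687, 0.00467 and 0.000371), the log2 change of CCCCCC turning from -1.05 to 1.80. After the subtraction with the block 0 variants passed in edgeR, with 254 at an unadjusted p under 0.05 (ACCACC -0.13, CCCCCC 2.49, edgeR adjusted p = 0.954 and 0.530).

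Over all variants the 100x counts turned on the scaling and the filter. The filter admits variants through the high libraries themselves. Among the 2757 that met it, 582 had no read in the low libraries and 0 had none in the high ones. Of 2757 tested variants edgeR called 1013 in high versus low and 730 in high versus background, all higher in the high fraction, 511 in ultra high versus background, 12 higher and 499 lower, and 421 by slope, 62 positive and 359 negative. The median log2 changes of all variants were 3.29, 1.84 and -3.88 in the first 3, and the median slope was -0.51. With groups without a read set to 3 reads the medians were 3.07, 1.88 and -2.37. The last covers only the 2416 variants with more than 3 reads in either group, so the set of variants changed as well. TMM scaling gave 456 and 328 calls, all higher, with medians of 1.79 and 0.05, then 0 calls in ultra high versus background, with 1041 at an unadjusted p under 0.05, and 290 by slope. DESeq2 called 59 in high versus low, 16 higher and 43 lower, and 100 in high versus background, 1 higher and 99 lower, with medians of 1.14 and -1.15. These directions are relative to the medians of each scaling. In ultra high versus background and by slope DESeq2 called 243 and 200. Requiring 50 reads in 4 libraries left 0 edgeR calls in high versus low and high versus background, with 97 and 25 at an unadjusted p under 0.05.

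With the replicate block edgeR called 2095 variants in high versus low, 1745 in high versus background, 1094 in ultra high versus background and 861 by slope. After the subtraction of cross-library reads, without the block, edgeR called 0 of 1487 variants in each of these 4, with 82, 20, 410 and 413 at an unadjusted p under 0.05. That loss of calls went with a larger spread, a common coefficient of variation of 2.92 against 1.68. With the subtraction and the block together, the slope alone of these kept calls. The purine class passed after the subtraction (camera adjusted p = 8.98e-13), its value as fitted in camera's model being 1.32 against 1.04 before, as did T at -3 (-1.28 against -1.15, camera adjusted p = 2.19e-10). As the mean of the 4 numbers the purine value was 1.22 ± 0.20, against 0.94 ± 0.09 before (log2, SD, n = 4). In all 9 classes passed, among them A at -3 with 0.96 (camera adjusted p = 1.09e-05) and in-frame ATG with 0.61 (camera adjusted p = 0.0229). Low and medium against background gave 0 edgeR calls on the deposited counts, with 357 and 254 at an unadjusted p under 0.05, 43 and 2 DESeq2 calls, and 479 and 136 edgeR calls with the replicate block.

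Leaving out single libraries moved these counts as well. Without high library 1, 2, 3 or 4 edgeR called 0, 187, 132 and 0 variants in high versus low and 0 in high versus background. Without ultra high library 1, 2, 3 or 4 it called 0 in ultra high versus background and 0, 0, 0 and 1 by slope, and without low library 1 it called 278 by slope.

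The high versus low difference in purines at -3 was not the same in the 3 arms. By read share it was 43.8 ± 3.02 percentage points in the CRISPR-Cas9 arm, 18.7 ± 1.38 in the PiggyBac arm and 67.8 ± 8.47 in the 100x arm (SD, n = 4 each). The differences between arms were -25.1 points for PiggyBac minus CRISPR-Cas9, 24.01 for 100x minus CRISPR-Cas9 and 49.1 for 100x minus PiggyBac (exact two-sided permutation test, p = 0.0286 each, adjusted p = 0.0286, with no overlap of the 4 and 4 values). With equal weight per variant the log2 differences were -1.22 and -1.33 for PiggyBac and 100x against CRISPR-Cas9 (exact permutation p = 0.0286, adjusted p = 0.0429) and -0.11 for 100x minus PiggyBac (exact permutation p = 0.114, adjusted p = 0.114). After the subtraction of cross-library reads the 100x value was 1.22 ± 0.20 (SD, n = 4). Its differences were then -1.05 against CRISPR-Cas9 (exact permutation p = 0.0286, adjusted p = 0.0429) and 0.17 against PiggyBac (exact permutation p = 0.171, adjusted p = 0.171), the last turned in sign. These tests were chosen after the data were seen.

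Variant by variant, the high versus low changes of the arms were positively correlated. Across 4096 variants the log2 changes of CRISPR-Cas9 and PiggyBac correlated with Pearson's r of 0.413 and Spearman's rho of 0.496, and 69.9% had the same sign. Across 2757 variants r was 0.250 and rho 0.214 for CRISPR-Cas9 and 100x, and r was 0.167 and rho 0.170 for PiggyBac and 100x. These 2 values of r were 0.580 and 0.370 over variants with a mean of at least 100 reads, and 0.415 and 0.293 after the subtraction of cross-library reads. Variants are not independent replicates, and these values describe the variants only. The arms share no library.

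Tests of the difference itself gave 0 variants for PiggyBac minus CRISPR-Cas9 (edgeR, 4096 tested, 555 at an unadjusted p under 0.05), and DESeq2 gave 122. Leaving out CRISPR-Cas9 low library 2, or the number 3 libraries, gave 1 edgeR call. For 100x minus CRISPR-Cas9 edgeR called 1578 variants, 1555 with the larger change in the 100x arm and 23 with the smaller, and DESeq2 called 1047. The smallest p-values belonged to ATGCAC, TGGCGG and CCGTGG (edgeR adjusted p = 0.00566 each). ATGCAC averaged 431 ± 276 CPM in the low and 102 ± 51.3 CPM in the high libraries of the CRISPR-Cas9 arm, and no read and 55.7 ± 79.0 CPM in those of the 100x arm (SD, n = 4 each). TGGCGG averaged 249 ± 215 and 27.4 ± 4.04 CPM in the CRISPR-Cas9 arm, and no read and 9.79 ± 8.49 CPM in the 100x arm. CCGTGG averaged 757 ± 638 and 39.2 ± 14.98 CPM in the CRISPR-Cas9 arm, and no read and 7.81 ± 3.17 CPM in the 100x arm (SD, n = 4 each). Over the 100x high libraries these were 533, 112 and 89 reads for ATGCAC, TGGCGG and CCGTGG. Variants hardly present in the other fractions of a number had a median of 17 to 25 reads in its high library. Without the libraries of number 1, 3 or 4 the count was 846, 893 and 958. After the subtraction of cross-library reads 0 of 4095 variants were called by edgeR, with 631 at an unadjusted p under 0.05.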

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

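Tests chosen only after the results were seen were the counts over other splits of the libraries between arms and of the fractions within each number, the tests of purines at -3 between arms, the comparison of reads between libraries of different arms, the tests of exchanged reads, dominant variants and copy number, and the use of an estimated correlation once the base at -3 was removed. The thinning of the 100x libraries and the removal of the base at -3 had been laid down before their results were seen.

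Purines at -3 separated high from low to different extents in the arms, by -25.1 percentage points of the read shares for PiggyBac minus CRISPR-Cas9, 24.01 for 100x minus CRISPR-Cas9 and 49.1 for 100x minus PiggyBac (exact permutation p = 0.0286, adjusted p = 0.0286). With equal weight per variant the differences were -1.22 and -1.33 on the log2 scale for PiggyBac and 100x against CRISPR-Cas9 (exact permutation p = 0.0286, adjusted p = 0.0429), and the second was -1.05 after the subtraction of cross-library reads (exact permutation p = 0.0286, adjusted p = 0.0429). As a cause of the smaller PiggyBac difference, reads exchanged between libraries would need 57.3% of reads from a common pool, and the low reads of some variants allow at most 20.9% in the 8 high and low libraries. A few variants taking most of the counts is argued against by the ratio of PiggyBac to CRISPR-Cas9 effects with equal weight per variant, 0.464. A candidate explanation is that PiggyBac cells carry several copies, which would shrink every position's effect alike. The 24 base effects of the arms correlated at 0.987 with a slope of 0.445. Single effects shrank unequally from the CRISPR-Cas9 to the PiggyBac arm. A at -3 went from 1.83 ± 0.05 to 0.86 ± 0.07, A at -4 from 0.39 ± 0.05 to 0.18 ± 0.04 and G at -6 from 0.40 ± 0.07 to 0.07 ± 0.04 (SD, n = 4). The 100x arm, without that delivery, gave nearly that slope too (0.439, correlation 0.904). But its base effects rest on the deposited counts, whose purine value of 0.94 became 1.22 after the subtraction, so its slope is not a like value. Even so, the 1.22 still lay below the purine value of 2.27 in the CRISPR-Cas9 arm. The correlation and slope therefore cannot single out copy number. Copy numbers were not measured, and a difference between integration sites stays open and untested.

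The change in high versus low differed between the 100x and CRISPR-Cas9 arms for 1578 variants in edgeR. Of 35 splits 1 was as large, and the highest other gave 0. Every other split mixed libraries of both arms, which also differ in composition (background Gini coefficients of 0.980 and 0.474). The splits therefore cannot decide whether chance gave that count. The 100x high libraries also listed more variants than their background libraries. Greater depth of the high libraries is argued against by the totals already. They held 2264019 to 3354722 reads against 2737128 to 5300552 in the background, fewer for each number. After thinning to one total the lowest high library still had 3003 variants with at least 10 reads and the highest background library 1046. Variants present in the 100x cells and missed in the other fractions would not favour 1 library of another arm, yet the smallest gap in rho between the best and the next library was 0.249. Reads of the same-numbered CRISPR-Cas9 medium library may account for the added variants, since it was the best match in 4 of 4 high libraries, while the step at which they would have entered was not tested. The calls of the difference between arms and of 100x high versus low were lost on the subtraction of these and other cross-library reads. For high versus low within the 100x arm this decides little. There the log2 change of AAAGAA went from 12.60 ± 3.74 to 12.56 ± 5.00 (SE) and that of AAAAAA from 6.40 to 3.65. In the same fit the common coefficient of variation rose from 1.68 to 2.92 and the tested variants fell from 2757 to 1487. The test between arms is a separate fit, whose log2 changes after the subtraction are not given here. Whether the difference between the arms is biological stays open.

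Several class effects in high versus low might follow from the base at -3 alone, which many class members share. With the means of each base at -3 removed, out-of-frame ATG (-0.59 in the CRISPR-Cas9 and -0.43 in the PiggyBac arm), at least 4 T (-0.58) and at most 1 match to GCCRCC (-0.49) in the CRISPR-Cas9 arm, and GTAAG or GTGAG (0.76) in the PiggyBac arm still passed (camera adjusted p between 0.00159 and 0.0179), which argues against the base at -3 as the whole cause there. So do, by the estimated correlation alone, CTG or GTG (-0.29 ± 0.08 and -0.16 ± 0.05; camera adjusted p = 0.0972 and 0.195, or 0.000625 and 0.00921 with an estimated correlation) in both arms and at most 1 match (-0.16 ± 0.02; camera adjusted p = 0.207, or 0.000600) in the PiggyBac arm, below 0 in 4 of 4 numbers each (SD, n = 4). The base at -3 could be the whole cause, as far as this test shows, for in-frame ATG (-0.10 and 0.059), at least 4 A (-0.091 and 0.061) and at least 5 matches to GCCRCC (0.24 and 0.13) in the CRISPR-Cas9 and PiggyBac arms, for GTAAG or GTGAG in the CRISPR-Cas9 arm (0.29) and for at least 4 T in the PiggyBac arm (-0.24), none of which passed by either correlation. In-frame stop codons (0.12 and 0.094) did not pass either, but that class pools unlike places. With the means removed, in the CRISPR-Cas9 arm those at -3 to -1 rose by 0.44 ± 0.07 (camera adjusted p = 0.0144). Those at -6 to -4 stood at -0.22 ± 0.11 (SD, n = 4). For the place -3 to -1 in that arm this argues against the base at -3 as the whole cause. Whether the remaining effects are biological is a hypothesis from the same data.

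Single libraries stood apart from the other 3 of their group in 4 of 75 tests, 5 measures in each of 15 groups, where chance alone gives about 1 in 20, or 3.75. In CRISPR-Cas9 ultra high library 2 the top 1% of variants took 67.9% of the reads, against 62.0% to 62.5% in the others, and in 100x high library 1 they took 74.3%, against 85.3% to 86.9%. Purines at -3 took 80.1% of the reads in PiggyBac ultra high library 3, against 64.5% to 66.3%, and 84.0% in 100x ultra high library 2, against 97.4% to 99.2%. No biological explanation was tested for these.

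For the other counts of variants, splits of the same libraries into groups of the same sizes were fitted. In ultra high versus background of the PiggyBac arm (1755, highest other 5) 1 of 35 splits was as large. Every other split mixed libraries of both fractions, which also differ in composition (Gini coefficients of 0.915 in ultra high and 0.396 in background). Those splits therefore cannot decide whether chance gave that count. For the slopes of the CRISPR-Cas9 and PiggyBac arms (2365, highest other 2201, and 1672, highest other 1516), 1 of 100 drawn splits was as large, with the same limit where a draw mixed ultra high libraries with others. With fractions permuted within each number it was also 1 of 100 for the CRISPR-Cas9 slope (highest other 2300). The highest other slopes kept the 4 ultra high libraries together, which points to that fraction as the structure they share. In ultra high versus background of the CRISPR-Cas9 arm (2557, highest other 0), and in ultra high versus background (511, highest other 0), high versus background (730, highest other 0) and high versus low (1013, highest other 0) of the 100x arm, 1 of 35 splits gave as many. But same-numbered libraries deviate together in each of these, and the 8 splits that part every same-numbered pair, where the others gave 0, are too few for a share under 0.05. By slope 3 of 100 drawn splits gave as many in the 100x arm (421, highest other 904), which points to a structure of the libraries. With fractions permuted within each number it was 9 of 100 (highest other 743), so chance cannot be excluded there. For the counts of 0 in high versus low, high, medium and low versus background of the CRISPR-Cas9 and PiggyBac arms, in low and medium versus background of the 100x arm and in PiggyBac minus CRISPR-Cas9, every split gives at least as many by construction (35 of 35), so the splits decide nothing. The highest other split gave 0 in each but 100x medium versus background, where another split called 140.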

How the results depend on the processing

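The subtraction of cross-library reads, with or without the replicate block, the sign permutation of base shares and the spread used for the correlations between arms were chosen only after the data were seen; the other alternatives were planned. Unless a clause below gives one, the cause of a change was not tested.

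DESeq2 moved 12 of 20 counts of variants by over 1.5 times. It called 556 in CRISPR-Cas9 high versus low and 113 in low versus background, 24 in PiggyBac high versus low and 11 in high versus background, 122 for PiggyBac minus CRISPR-Cas9 and 1047 for 100x minus CRISPR-Cas9. In the 100x arm it called 59 in high versus low, 100 in high versus background, 2 and 43 in medium and low versus background, 243 in ultra high versus background and 200 by slope. The other 8 DESeq2 counts lay within 1.5 times the main ones. TMM scaling moved 4 of 20 counts, CRISPR-Cas9 ultra high versus background to 1637 and 100x high versus low, high versus background and ultra high versus background to 456, 328 and 0. Of the variants called in ultra high versus background, 1110 in the CRISPR-Cas9 arm and 1036 in the PiggyBac arm were also called with TMM scaling.

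A filter of 50 reads gave 0 calls in 100x high versus low and high versus background and changed no other count by over 1.5 times. Without a filter these gave 2054 and 1908, and ultra high versus background and the slope of the 100x arm gave 0 and 0. With only the compared fractions, ultra high versus background gave 917 in the PiggyBac arm and 215 in the 100x arm. The replicate block gave 2095 calls in 100x high versus low, 1745, 136, 479 and 1094 in high, medium, low and ultra high versus background, and 861 by slope. It changed no count of the other arms or of the differences between arms by over 1.5 times. After subtraction, high versus low, high versus background, ultra high versus background and slope of the 100x arm gave 0, 0, 0 and 0, or 0, 0, 0 and 228 with the block, and 100x minus CRISPR-Cas9 gave 0. In the other arms the subtraction left 2406 and 1482 calls in ultra high versus background and 2202 and 1388 by slope.

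Leaving out libraries gave 0 to 8 calls in CRISPR-Cas9 high versus low (8 without low library 4), 0 to 1 for PiggyBac minus CRISPR-Cas9 (1 without CRISPR-Cas9 low library 2, or number 3) and 846 to 1577 for 100x minus CRISPR-Cas9 (846, 893 and 958 without number 1, 3 and 4). In the 100x arm the ranges were 0 to 925 in high versus low, 0 to 705 in high versus background, 0 to 465 in ultra high versus background and 0 to 477 by slope. Each number left out gave 0 in all 4. The filter was applied again after each removal, so the set of tested variants changed too (1742 to 1891 with a number left out, against 2757). Without high library 1, 2, 3 or 4 there were 0, 187, 132 and 0 in high versus low and 0 in high versus background. Without ultra high library 1, 2, 3 or 4 there were 0 in ultra high versus background and 0, 0, 0 and 1 by slope, and without low library 1 there were 278 by slope. Calls in ultra high versus background stayed between 2396 and 2744 in the CRISPR-Cas9 arm and between 1531 and 2108 in the PiggyBac arm, and by slope between 2231 and 2588 and between 1462 and 2036.

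Of the 108 class tests, TMM scaling, prior counts of 0.5 and 5 and the replicate block left 100, 104, 104 and 102 with the same call and direction. The purine class of the 100x arm missed the threshold with a prior count of 5 (camera adjusted p = 0.0628). CTG or GTG in PiggyBac high versus low passed with TMM scaling (adjusted p = 0.0475), the replicate block (0.0487) and without number 4 (0.0338). Only sets under test are read by fry, which asks whether the variants of a class move one way and not whether they move more than others, and it passed 18 classes in high versus low and 8 by slope in the 100x arm. It added 33 calls in all and ended 4. In high versus low it ended CTG or GTG in the CRISPR-Cas9 arm (fry adjusted p = 0.272). In the PiggyBac arm it ended in-frame ATG and at least 4 T (fry adjusted p = 0.0902 and 0.0659). By slope it ended at most 1 match in the 100x arm (fry adjusted p = 0.153). The number of passing classes in 100x high versus low was 7 with the block, 9 after subtraction and 7 to 9 with a number left out (9, 8, 7 and 8 without number 1, 2, 3 and 4), and by slope 8 to 10 (10 without number 3).

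Coverage differences kept their direction in all alternatives. With a minimum of 100 reads the PiggyBac minus CRISPR-Cas9 difference was 487 variants and passed, and after thinning the difference in variants with at least 1 read was 4.25 and did not. With a number left out the smallest exact p is 0.1, so no such test can pass. The differences then ran, for 100x minus CRISPR-Cas9 and 100x minus PiggyBac, from -1548 to -1342 and -1555 to -1345 variants with at least 1 read, -2944 to -2855 and -2972 to -2874 with at least 10, 0.501 to 0.511 and 0.583 to 0.587 in Gini coefficient and 66.9 to 69.6 and 67.5 to 70.9 points in the top 1%. For PiggyBac minus CRISPR-Cas9 they ran from 3 to 6.67 variants and from -0.0859 to -0.0714 in Gini coefficient. For base shares the smallest p was 0.125 with the replicate block and 0.1 with a number left out, so none could pass, and with each variant counted once the smallest adjusted p was 0.0508.

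The correlation between arms, CRISPR-Cas9 with PiggyBac, CRISPR-Cas9 with 100x and PiggyBac with 100x in this order, ran from 0.361 to 0.385, 0.286 to 0.319 and 0.193 to 0.221 with a number left out. With at least 100 reads the values with 100x were 0.580 and 0.370, by slope the first 2 were 0.288 and 0.283, and after subtraction the values with 100x were 0.415 and 0.293. All stayed positive.

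Of the named variants, TTTTTT kept its sign in all alternatives of CRISPR-Cas9 high versus low and passed over all variants in DESeq2 alone. The 5 variants named first in the 100x arm lost their calls without high library 1, and after the subtraction 4 lost theirs with log2 changes of 12.56, 11.68, 10.85 and 10.79 and larger SEs (GGAATT 4.37 and AACATA 8.48 with the block as well), and TGAAGG was no longer tested. Depth limits the statements on rare variants: a group of the 100x arm with no read allows up to 0.840 CPM in low and 0.812 CPM in ultra high.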

Other observations

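The tests by place of a triplet and the models of base effects were chosen only after the results were seen, and the tests of the base at -3 had been laid down before.

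The values of ATG in high versus low are given by its place within the 6 bases, with no test between places. ATG at -6 to -4, the in-frame place that does not touch -3, did not pass (-0.13 ± 0.14 in the CRISPR-Cas9 and 0.08 ± 0.22 in the PiggyBac arm, SD, n = 4; camera adjusted p = 0.650 and 0.776). ATG at -5 to -3, with the means of each base at -3 removed, fell by 1.25 ± 0.08 in the CRISPR-Cas9 arm (camera adjusted p = 1.16e-08; SD, n = 4). It fell by 0.61 ± 0.08 in the PiggyBac arm (camera adjusted p = 1.11e-05; log2, SD, n = 4, below 0 in 4 of 4 numbers of each arm). ATG at -4 to -2 and at -3 to -1 did not pass in the CRISPR-Cas9 arm (0.08 ± 0.12 and -0.09 ± 0.38, SD, n = 4; camera adjusted p = 0.740 and 0.704), nor in the PiggyBac arm (-0.24 ± 0.29 and -0.0074 ± 0.18, SD, n = 4; camera adjusted p = 0.224 and 0.704). Without the removal ATG at -5 to -3 did not pass (-0.30 ± 0.12 in the CRISPR-Cas9 and -0.19 ± 0.09 in the PiggyBac arm, SD, n = 4; camera adjusted p = 0.400 and 0.353). ATG at -4 to -2 then fell by 1.42 ± 0.16 and 0.97 ± 0.28 (camera adjusted p = 6.72e-07 and 7.89e-09), and ATG at -3 to -1 rose by 1.32 ± 0.41 and 0.67 ± 0.21 (camera adjusted p = 6.88e-06 and 0.000201; SD, n = 4). A stop codon at -3 to -1 rose by 0.44 ± 0.07 in the CRISPR-Cas9 arm after the same removal (camera adjusted p = 0.0144; SD, n = 4). Without the removal the class fell by 1.11 ± 0.05 (camera adjusted p = 9.07e-07; SD, n = 4), so the sign of that class rested on T at -3. A stop codon at -6 to -4 did not pass (-0.22 ± 0.11 in the CRISPR-Cas9 and -0.01 ± 0.08 in the PiggyBac arm, SD, n = 4; camera adjusted p = 0.499 and 0.899). For the one at -3 to -1 in the PiggyBac arm the value was -0.55 ± 0.07 without the removal (SD, n = 4; camera adjusted p = 2.39e-05), and after it 0.20 ± 0.08 (SD, n = 4; camera adjusted p = 0.0611, or 0.0309 with an estimated correlation).

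A model that adds 1 effect per base and position described 57.3% of the variance between variants of the log2 change in high versus low in the CRISPR-Cas9 arm, 35.1% in the PiggyBac arm and 15.1% in the 100x arm. The base at -3 alone described 45.4%, 29.97% and 9.73%. The additive model of the CRISPR-Cas9 arm correlated with the measured PiggyBac changes at r = 0.584, where the measured changes correlated with each other at 0.484, and the model of the PiggyBac arm correlated with the measured CRISPR-Cas9 changes at 0.747. The changes used here are means over the 4 numbers of the log2 ratio of CPM, not the edgeR estimates. These correlations are across variants, which are not independent replicates. Of the 24 base effects, 22 had the same sign in both arms.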
